A study of Mus musculus with 6 samples.

How the data were processed

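RNA sequencing libraries of mouse alveolar macrophages from lung were read in 2 groups, 3 control and 3 Rack1 myeloid knockout, as the labels group them. Total RNA was extracted with TRIzol and libraries were made with a NEBNext Ultra kit, per the labels' protocols. The submitters' processing notes name cutadapt, FastQC, HISAT2, StringTie, DESeq2 and edgeR and the GRCm38 build, without versions or the role of each tool. The deposited table holds an estimated (expected) count and an FPKM value per gene and library, per the file headers. The expected counts are whole numbers as deposited. They were compared with the deposited FPKM times transcript length times a constant per library, in genes with 1 transcript and over 500 units. Of these genes, 87.1% to 89.8% per library lay within 1% of that product. Genes with several transcripts were not compared. The counts were therefore read as estimates from assembled transcripts and not as tallies of reads. A read pair was worth about 4 of these units. No batch, date or handling of the libraries is given in the labels.

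All values in the text were computed from the deposited table. The test planned for FPKM was limma on log2(FPKM + 1), with edgeR to be used where the table held raw read counts. The deposited counts were read as estimates, so that condition was not strictly met. The main results nonetheless came from edgeR on these estimated counts, which departs from the plan, and limma is given as an alternative. Genes were kept by edgeR's expression filter with its default settings, counts were scaled by TMM, and a quasi-likelihood test compared the groups with no covariate. P-values were adjusted over all genes tested by the Benjamini-Hochberg method at 0.05. Fold changes are those of edgeR's fit with its default prior count of 0.125, and their standard errors were taken as the log2 fold change over the square root of the F statistic. Counts-per-million (CPM) used TMM-scaled library sizes, and the log2 CPM values behind list tests, list means and correlations used a prior count of 2. A gene was called higher or lower in knockout only where it passed this test. R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used. Coordinates are those of the deposited table, and 26359 of its 26428 genes were found in the GENCODE M21 annotation.

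The groups, the design, the alternatives planned, the 41 gene lists and the rule for naming genes were chosen before the data were examined. The lists cover macrophage identity and state, inflammation, interferon, stress, ribosome and translation, lipid and energy metabolism, cell division, signalling partners of RACK1 and markers of other cells, and a result of each is given. Lists of at least 5 tested genes were tested with camera at a preset correlation between genes of 0.01, and again with an estimated correlation and with fry. Counts within a list were also adjusted over the list alone. Genes named are Rack1, then the 12 largest changes per direction among called genes with a mean FPKM of at least 5 in the higher group and no overlap between groups, then from each list up to 4 members with the smallest p and its first 3 symbols. The text names only part of the list members that the rule allows. Members of a list with few calls, sex-linked, globin, intestinal and smooth muscle genes, and other genes outside the rule were chosen after their values were seen, as were the colon and smooth muscle lists. GO, KEGG and Reactome annotation carried by the deposited table was tested with one-sided Fisher's exact tests on terms of 10 to 500 tested genes.

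Alternatives planned were limma on log2(FPKM + 1) with other pseudocounts, scalings, filters, robust fitting and library weights, edgeR without its filter or with a higher one, median-of-ratios size factors, DESeq2, a replicate block, and leaving out each library. Chosen after seeing the data were scaling to library totals, division of the counts by 4, a GC and length correction, a minimum of 10 CPM, and leaving out genes with no count in 1 whole group. The gene test was checked on simulated counts for 14286 genes, where edgeR recovered 60% of 2-fold and 88% of 4-fold changes with 6 false calls among 154. The changed genes were drawn only from those above a minimum mean count, with equal numbers up and down. The recovery therefore does not cover genes near the floors. Floors for a group at 0 were 3 read pairs, or 12 units, per library, and they cover counting error only.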

Results

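Gene expression was measured by RNA sequencing in alveolar macrophages, the resident phagocytes of the lung air spaces, from mice with a myeloid knockout of Rack1 and from control mice. RACK1 is a scaffold protein of the small ribosomal subunit that also binds protein kinase C. The labels give 6 libraries in 2 groups. The 3 control libraries carry the genotype label Rack1F/- and the 3 knockout libraries the label Rack1{delta}Mye. Nothing in the labels says that the libraries of a group came from separate animals, so all p-values measure the spread between these samples. Estimated counts summed to 56763356, 54871157 and 66163430 units in control replicates 1, 2 and 3 and to 56082536, 51894849 and 55191067 units in knockout replicates 1, 2 and 3. A read pair was worth about 4 of these units. Of 26428 genes in the deposited table, 14797 had enough counts to be tested. Pearson correlations of log2 values across genes, which are not independent replicates, were 0.952 to 0.966 within groups and 0.924 to 0.936 between groups. Libraries of a group differed by more than counting noise, with a chi-square per degree of freedom of 17.2 to 49.6.

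Rack1, the targeted gene, was lower in every knockout library than in every control library. The gene (ENSMUSG00000020372) lies on chromosome 11 at 48800332 to 48806093 on the plus strand of GRCm38, per the deposited table. It stood at 77.3, 83.5 and 81.1 counts-per-million (CPM) in control replicates 1, 2 and 3 and at 38.6, 38.2 and 34.2 CPM in knockout replicates 1, 2 and 3. The means were 80.6 ± 3.14 CPM (SD, n = 3) and 37.0 ± 2.45 CPM (SD, n = 3), a 2.18-fold difference. Its log2 fold change was -1.12 with a standard error of 0.114 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.000207). Which part of Rack1 was deleted is not given in the sources used here, so reads outside that part can contribute to the knockout values.

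The comparison of knockout with control asked which genes alveolar macrophages express at another level when Rack1 is deleted in the myeloid lineage. Spp1, which encodes the secreted matricellular protein osteopontin, rose 18.6-fold, from 959.8 ± 92.9 to 17850 ± 2999 CPM (SD, n = 3 per group). The growth factor gene Igf1 rose 8.96-fold, from 13.6 ± 1.27 to 121.4 ± 16.2 CPM, and Mmp12, which encodes macrophage elastase, rose 12.2-fold, from 4.31 ± 0.984 to 52.4 ± 15.1 CPM. Transferrin (Trf) fell 3.80-fold, from 2487 ± 565.8 to 654 ± 132.3 CPM, and Gal, which encodes the neuropeptide galanin, fell 5.61-fold, from 310.0 ± 43.9 to 55.3 ± 21.3 CPM. In all, 878 genes were higher and 889 lower in knockout, together 11.9% of the genes tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and 456 and 304 of them by at least 2-fold. Scaling to library totals in place of TMM gave 290 higher and 933 lower, so that 23.7% of the calls were higher against 49.7% with TMM, because TMM moved all log2 fold changes by 0.32. The limma test on log2(FPKM + 1) as deposited, planned for a table without raw read counts, gave 239 higher and 1150 lower, 17.2% of its calls higher. Limma on FPKM divided by size factors gave 727 and 674, or 51.9% higher. All 3 knockout libraries lay on one side of all 3 control libraries for 31.2% of genes, against 10% by chance. The counts fell to 455 higher and 372 lower without control replicate 1, 537 and 450 without control replicate 2, 691 and 565 without control replicate 3, 631 and 519 without knockout replicate 1, 575 and 478 without knockout replicate 2, and 615 and 551 without knockout replicate 3. The libraries also differed in sex-linked transcripts, which were looked at after the values were seen. The Y-linked Eif2s3y stood at 16.0 CPM in knockout replicate 1 and 2.68 CPM in knockout replicate 2, against 0.357 to 0.681 CPM elsewhere. Its call was lost without control replicates 1, 2 or 3 or knockout replicate 1 (edgeR adjusted p = 0.0909, 0.0881, 0.0729 and 0.111), and its log2 fold change fell from 3.83 to 1.90 without knockout replicate 1. Ddx3y, also Y-linked, stood at 8.45 and 3.16 CPM in knockout replicates 1 and 2 and at 0.283 to 0.532 CPM elsewhere (edgeR adjusted p = 0.0477). Xist, transcribed from the inactive X chromosome, stood at 0.741 CPM in knockout replicate 1 against 10.4 to 70.6 CPM elsewhere. Tsix stood at 0.330 CPM in control replicate 1 and 1.37 CPM in knockout replicate 1, against 22.8 to 46.7 CPM elsewhere. The labels do not give the sex of the animals, so sex was not in the test and cannot be fully parted from genotype.

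Among the 12 named genes with the largest rises were receptors, lipid enzymes and secreted proteins. The fatty acid hydroxylase genes Cyp4a12b and Cyp4a12a had log2 fold changes of 6.31 and 5.62; their sequences are close to identical, so the split of reads between them is uncertain. Syngr1, which encodes a vesicle membrane protein, rose from 1.71 ± 0.444 to 57.0 ± 9.04 CPM (SD, n = 3 per group). The chemokine receptor genes Cxcr1 and Cxcr2 rose from 3.28 ± 0.772 to 61.1 ± 15.1 CPM and from 1.78 ± 0.313 to 19.8 ± 6.18 CPM. Plpp3, which encodes a lipid phosphate phosphatase, rose 12.8-fold, and the interferon-inducible oligoadenylate synthetase gene Oas1g rose 9.55-fold. The acute phase gene Orm1 and the neuropeptide gene Npy rose from 0.252 ± 0.225 to 4.49 ± 2.91 CPM and from 0.581 ± 0.148 to 4.94 ± 1.05 CPM. Adjusted p-values of these 12 genes ran from 2.67e-06 for Syngr1 and Igf1 to 0.00954 for Orm1 (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment).

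Among the 12 named genes with the largest falls, metabolic, receptor and epithelial genes stood side by side. Gpd1, which encodes the cytosolic glycerol phosphate dehydrogenase, fell from 22.4 ± 4.15 to 1.94 ± 0.329 CPM (SD, n = 3 per group), and Cpne5, a copine gene, fell from 86.2 ± 15.6 to 10.8 ± 0.924 CPM. Fcgr2b, the inhibitory Fc receptor for immunoglobulin G, fell 3.80-fold, and the C-type lectin receptor gene Clec4a3 fell 3.60-fold. Batf3, a transcription factor gene, fell from 14.9 ± 1.54 to 2.79 ± 1.55 CPM. The serine protease gene Klk8, the lipase gene Pnpla5 and Emb, which encodes a partner of monocarboxylate transporters, had log2 fold changes of -2.55, -1.98 and -1.79. The epithelial adhesion gene Epcam fell from 18.9 ± 3.39 to 3.97 ± 1.15 CPM, and Lypd8, a gene of colon epithelium, from 7.67 ± 1.16 to 0.121 ± 0.169 CPM. Transcripts of a list of colon epithelium genes, Lypd8 among them, summed to 43.1 to 47.3 CPM in the control libraries. Adjusted p-values of these 12 genes ran from 4.08e-06 for Cpne5 to 0.00155 for Batf3 (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment).

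**Figure D1:**
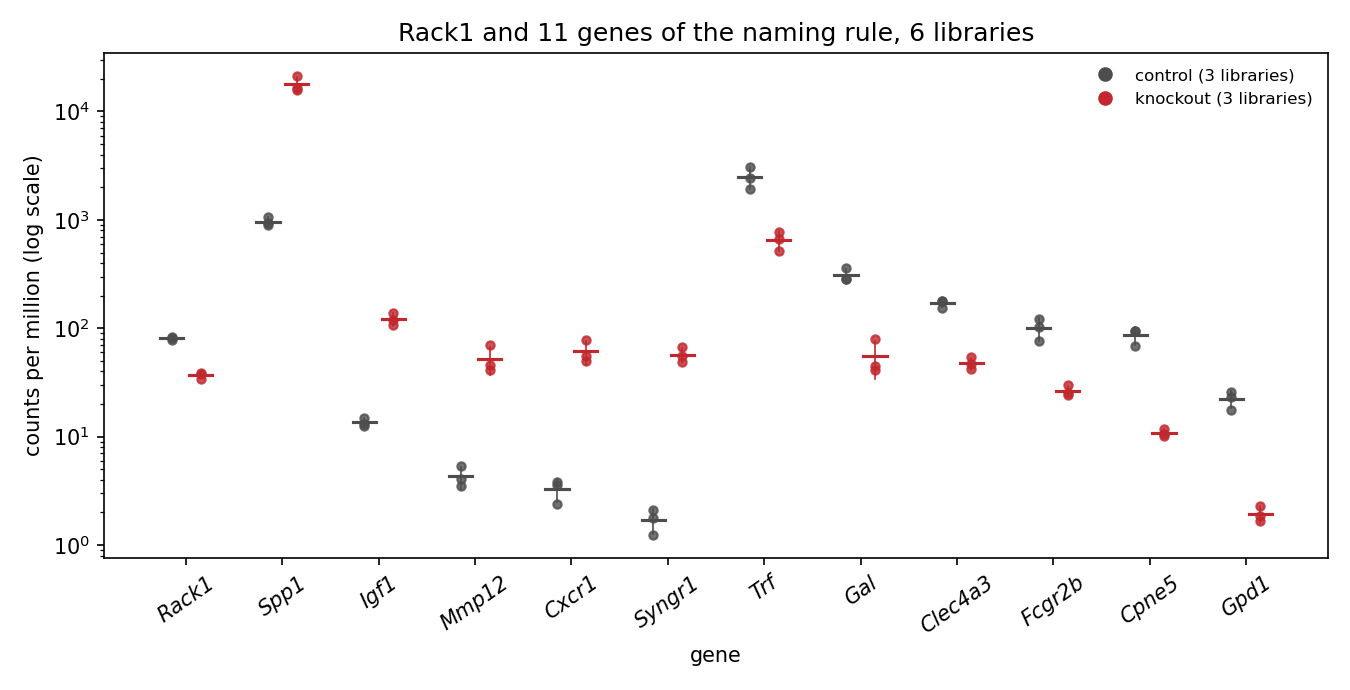
Counts-per-million values (log axis) of Rack1 and 11 named genes in each of the 6 libraries, with control in grey and knockout in red; horizontal bars are group means and vertical bars ± 1 SD over 3 libraries. Spp1 stood at 888.4 to 1065 CPM in the control libraries and at 15670 to 21270 CPM in the knockout libraries, and Rack1 at 77.3 to 83.5 and 34.2 to 38.6 CPM.

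Of 29 tested genes of pro-fibrotic and lipid-associated macrophages, 9 were higher in knockout, 3 were lower and 17 did not pass the test. Beside Spp1, Igf1 and Mmp12, the higher ones included Trem2, a lipid-sensing receptor gene, which rose from 68.7 ± 2.49 to 282.5 ± 39.0 CPM (SD, n = 3 per group), and Cd63, a tetraspanin gene of late endosomes, with a log2 fold change of 2.69. Members that fell included Fn1, which encodes fibronectin, and Tgfbi, an extracellular matrix gene, at log2 fold changes of -1.95 and -0.72. Gpnmb, a glycoprotein gene of the same state, was at 0.31 (edgeR adjusted p = 0.245). Adjusted over the list alone, 12 members were higher and 3 lower. The median log2 fold change was 0.61 (camera, preset correlation, Benjamini-Hochberg adjusted p = 0.000184); it was 1.04 without control replicate 1, 0.41 on library totals, 0.37 with limma after quantile normalization, 0.17 with limma on log2(FPKM + 1) and 0.10 with limma without a filter. With an estimated correlation the adjusted p was 0.52.

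Inflammatory cytokine and chemokine genes were higher as a list by camera with the preset correlation but not with an estimated one (adjusted p = 0.52), with 11 of 33 tested members higher and 1 lower. The chemokine genes Ccl9 and Ccl3 rose from 92.2 ± 5.59 to 451.3 ± 89.3 CPM and from 20.4 ± 2.39 to 72.6 ± 11.1 CPM (SD, n = 3 per group). Ccl6, one of the most abundant transcripts in these libraries, rose from 18410 ± 5997 to 64440 ± 13730 CPM. The interleukin genes Il1a and Il1b had log2 fold changes of 1.56 and 0.99; Il1b lost its call without control replicate 1 or knockout replicate 2 (edgeR adjusted p = 0.0706 and 0.0564). The chemokine gene Cxcl14 fell, with a log2 fold change of -1.75. Tnf and Il6, which encode further inflammatory cytokines, were at 0.85 and -0.21 (edgeR adjusted p = 0.0688 and 0.881). Adjusted over the list alone, 16 members were higher and 1 lower. The median log2 fold change was 0.76 (camera, preset correlation, Benjamini-Hochberg adjusted p = 0.000433). It was 0.47 on library totals, 0.42 with limma on log2(FPKM + 1), 0.17 with limma without a filter and 0.07 with limma and library weights. With limma on FPKM divided by size factors it was 0.74, and after quantile normalization 0.73.

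Interferon-stimulated genes were higher in all 3 knockout libraries, most in knockout replicate 2. Of 37 tested members 17 rose and 0 fell, and 36 had a positive log2 fold change. The ubiquitin-like Isg15 rose from 0.886 ± 0.189 to 3.40 ± 0.634 CPM, the antiviral Ifit1 from 3.18 ± 0.734 to 8.06 ± 2.11 CPM and Oas1a, a further oligoadenylate synthetase gene, from 21.6 ± 1.12 to 63.6 ± 18.4 CPM (SD, n = 3 per group). Irf7, a transcription factor gene of the interferon response, stood at 33.3 CPM in knockout replicate 2 and at 9.28 and 9.67 CPM in knockout replicates 1 and 3, against 4.73 to 6.08 CPM in control. Its log2 fold change was 1.65, and 0.76 without knockout replicate 2. Its call was lost without control replicate 1, 2 or 3 (edgeR adjusted p = 0.103, 0.0877 and 0.113). The mean log2 value of the list, relative to the control mean, was 0.72, 1.65 and 0.96 in knockout replicates 1, 2 and 3 and -0.06 to 0.04 in the control libraries. Adjusted over the list alone, 23 members were higher and 0 lower, and 0 were lower over all genes tested. The median log2 fold change was 1.17 (camera, preset correlation, Benjamini-Hochberg adjusted p = 5.87e-11) and 0.71 without knockout replicate 2 (adjusted p = 2.91e-10 by camera). It was 0.58 with limma on log2(FPKM + 1), 0.22 with limma without a filter and 0.20 with limma and library weights. With limma on FPKM divided by size factors it was 0.87, and after quantile normalization 0.85. With an estimated correlation the camera adjusted p was 0.62.

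Heat shock genes and genes of apoptosis and the p53 pathway were higher as lists by camera with the preset correlation but not with an estimated one (adjusted p = 0.62 and 0.52). Of 16 heat shock genes 7 rose and 0 fell, and 8 were higher adjusted over the list alone. The chaperone genes Bag3 and Hsp90ab1 rose from 13.4 ± 1.04 to 35.3 ± 0.650 CPM and from 659.5 ± 30.3 to 1366 ± 195.5 CPM (SD, n = 3 per group). The inducible chaperone genes Hspa1a and Hspa1b, near-identical copies whose reads cannot be fully parted, had log2 fold changes of 2.16 and 2.03, and lost their calls without control replicate 1 (edgeR adjusted p = 0.0505 and 0.0518). The heat shock median was 0.54 (camera, preset correlation, Benjamini-Hochberg adjusted p = 0.00206), 0.35 without knockout replicate 1, 0.19 on library totals and 0.17 with limma on log2(FPKM + 1). With limma on FPKM divided by size factors it was 0.45, and after quantile normalization 0.4. Of 26 apoptosis and p53 genes 6 rose and 2 fell, and 7 and 2 passed adjusted over the list alone. Phlda3 and Cdkn1a, both p53 targets, rose from 112.3 ± 14.4 to 375.7 ± 27.8 CPM and from 279.9 ± 17.6 to 835.6 ± 59.5 CPM. The median of this list was 0.41 (camera, preset correlation, Benjamini-Hochberg adjusted p = 0.032). It was 0.10 on library totals, 0.08 with limma on log2(FPKM + 1) and 0.02 with limma and library weights. With limma on FPKM divided by size factors it was 0.34, and after quantile normalization 0.3. Its call was lost without control replicate 1, control replicate 3, knockout replicate 1 or knockout replicate 2, at camera adjusted p = 0.0575, 0.0809, 0.0532 and 0.056; the median was 0.26 without knockout replicate 1. It was also lost on genes with a mean FPKM of at least 5 (camera adjusted p = 0.115) and with limma on unfiltered values (camera adjusted p = 0.0723). Genes of the integrated stress response went both ways, with 7 of 26 higher and 3 lower (8 and 3 adjusted over the list alone) and a camera adjusted p of 0.294. Gdf15, a stress-induced cytokine gene, rose from 24.5 ± 1.20 to 153.4 ± 25.4 CPM, and Phgdh, the first enzyme of serine synthesis, fell from 132.5 ± 12.4 to 58.5 ± 15.3 CPM.

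Genes of cell division and nuclear genes of oxidative phosphorylation were lower as lists by camera with the preset correlation, but not by fry (adjusted p = 0.1 and 0.13) or by camera with an estimated correlation (adjusted p = 0.64 for both). Of 44 proliferation genes 0 rose and 13 fell, and 0 and 22 passed adjusted over the list alone. Cdc20, an activator of the anaphase-promoting complex, fell from 11.8 ± 1.74 to 5.27 ± 0.624 CPM (SD, n = 3 per group). Tk1, the thymidine kinase gene, had a log2 fold change of -1.16. Ccnb1, which encodes a mitotic cyclin, had a log2 fold change of -0.95, and Mki67 was at -0.61 (edgeR adjusted p = 0.0945). The proliferation median was -0.55 (camera, preset correlation, Benjamini-Hochberg adjusted p = 8.62e-08), and -0.92 with scaling to library totals. Of 69 nuclear genes of oxidative phosphorylation 0 rose and 12 fell, and 0 and 15 passed adjusted over the list alone. Cox7c, a subunit of cytochrome c oxidase, fell from 162.4 ± 22.7 to 91.4 ± 6.84 CPM. The median of this list was -0.25 (camera, preset correlation, Benjamini-Hochberg adjusted p = 1.48e-06), and -0.55 with scaling to library totals. Of 15 mitochondrially encoded transcripts 0 passed the edgeR test in either direction, over all genes or adjusted over the list alone, and the camera adjusted p was 0.629.

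Genes of alveolar macrophage identity went both ways, with 9 of 36 higher and 7 lower (11 and 9 adjusted over the list alone). Car4, which encodes a carbonic anhydrase, rose from 1047 ± 111.2 to 6024 ± 1095 CPM, and the scavenger receptor gene Marco from 1016 ± 102.6 to 4383 ± 1013 CPM (SD, n = 3 per group). Slc39a2, a zinc transporter gene, had a log2 fold change of 1.59. Siglecf, the sialic acid receptor used to identify these cells, fell from 164.6 ± 9.80 to 103.2 ± 8.12 CPM, and Cidec, a lipid droplet gene, from 407.1 ± 40.5 to 141.6 ± 30.3 CPM. Pparg, a transcription factor gene these cells depend on, was at -0.46 (edgeR adjusted p = 0.109). Dmbt1, which is also a gene of intestinal epithelium, had no count in knockout and was at least 17.2-fold lower, against a floor of 3 read pairs per library. The camera adjusted p of the list was 0.629. Phagocytosis and efferocytosis receptors also went both ways, with 6 of 33 higher and 5 lower (7 and 5 adjusted over the list alone; camera adjusted p = 0.738). Mfge8, a bridging molecule for apoptotic cells, rose from 16.5 ± 2.86 to 131.3 ± 10.4 CPM, and the scavenger receptor gene Msr1 from 21.2 ± 2.98 to 75.8 ± 10.2 CPM.

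**Figure D2:**
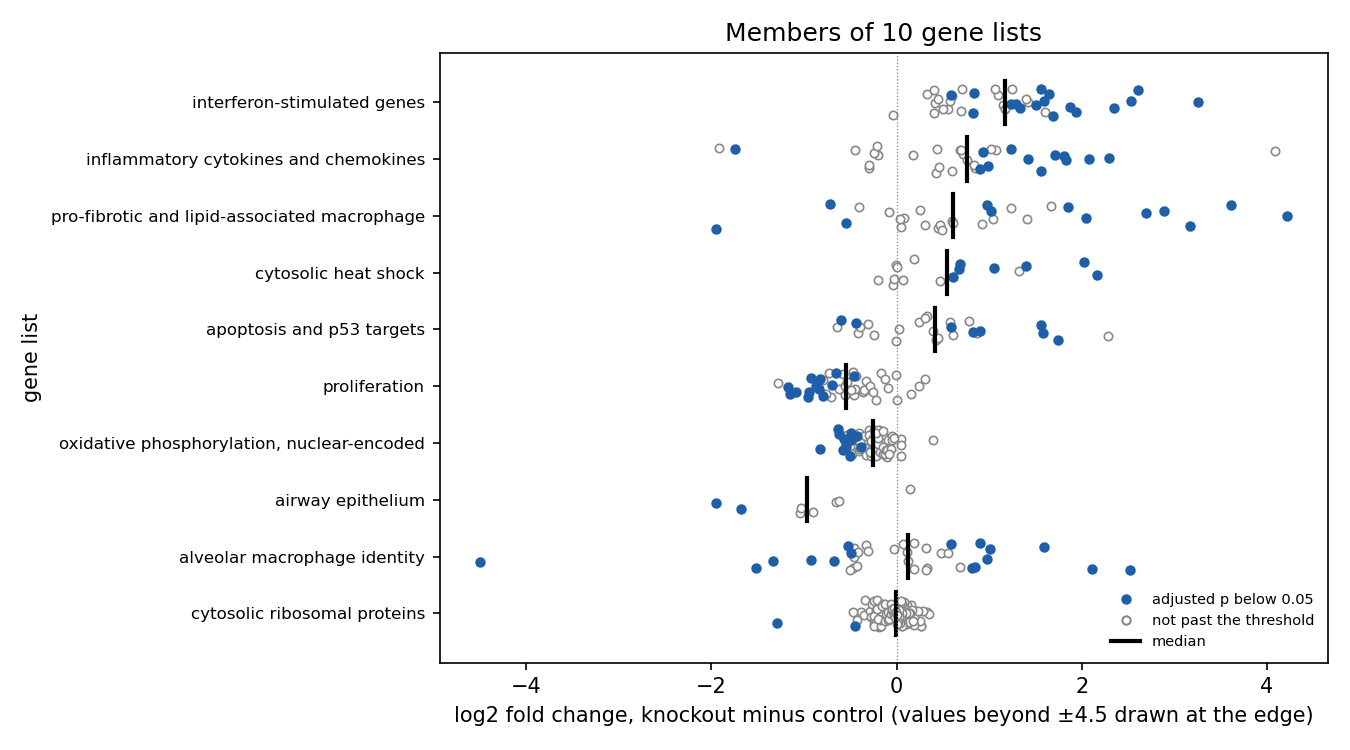
Log2 fold changes (knockout minus control) of the tested members of 10 gene lists, with 1 point per gene; filled points had an edgeR adjusted p under 0.05, black bars are list medians, and values beyond the axis are drawn at its edge. The median was 1.17 for interferon-stimulated genes, -0.55 for proliferation and -0.01 for cytosolic ribosomal proteins.

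Cytosolic ribosomal protein genes, the partners of RACK1 in the ribosome, centred on 0, with 0 of 79 higher and 2 lower, Rps3a1 and Rpl7a, and 0 in either direction adjusted over the list alone. Both lost their calls when libraries were left out, Rps3a1 without control replicates 1 or 2 or any knockout library (edgeR adjusted p = 0.0981, 0.129, 0.0594, 0.101 and 0.103) and Rpl7a without any control library or knockout replicates 1 or 2 (edgeR adjusted p = 0.202, 0.0735, 0.0681, 0.121 and 0.143). The median was -0.01 with TMM and -0.33 with scaling to library totals (camera adjusted p = 0.6 and 0.0585). Of 42 translation factor genes 4 rose and 2 fell (4 and 2 adjusted over the list alone; camera adjusted p = 0.748). Eif4h, a cofactor of the initiation helicase, fell from 83.0 ± 2.33 to 52.8 ± 0.238 CPM and Eif5, an initiation factor gene, rose from 251.1 ± 27.6 to 480.2 ± 105.4 CPM (SD, n = 3 per group). Of 20 ribosome quality control genes 1 rose and 0 fell (1 and 0 adjusted over the list alone; camera adjusted p = 0.925). The 1 was Usp10, a deubiquitinase gene, whose call was lost without control replicates 1 or 2 or any knockout library (edgeR adjusted p = 0.0904, 0.0885, 0.0636, 0.0657 and 0.0776).

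Lipid gene lists were not called by camera, though fry called lipid efflux and liver X receptor targets (adjusted p = 0.034), and single members changed. Of 33 genes of fatty acid oxidation and PPAR targets 5 rose and 7 fell (6 and 8 adjusted over the list alone; camera adjusted p = 0.629). Pdk4, an inhibitor of pyruvate dehydrogenase, and Angptl4, a lipoprotein lipase inhibitor, rose from 1.03 ± 0.0796 to 8.35 ± 2.55 CPM and from 114.8 ± 7.44 to 263.1 ± 24.8 CPM (SD, n = 3 per group), while Etfa, an electron carrier of fatty acid oxidation, fell from 95.4 ± 6.60 to 54.2 ± 3.48 CPM. Of 17 lipid efflux and liver X receptor targets 4 rose and 1 fell (7 and 2 adjusted over the list alone; camera adjusted p = 0.0563); Pltp, a phospholipid transfer protein gene, rose from 115.9 ± 6.34 to 247.6 ± 25.3 CPM. Of 24 cholesterol biosynthesis genes 2 rose and 4 fell (3 and 4 adjusted over the list alone; camera adjusted p = 0.163). Of 17 genes of phospholipid and surfactant catabolism 3 rose and 5 fell (3 and 8 adjusted over the list alone; camera adjusted p = 0.629); Pla2g7, which encodes a secreted phospholipase, rose from 8.96 ± 3.93 to 35.7 ± 7.88 CPM.

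The remaining lists on macrophage state were not called by camera, though fry called the immediate early genes (adjusted p = 0.0067). Among genes of monocyte-derived and interstitial macrophages, 5 of 33 rose and 3 fell (7 and 3 adjusted over the list alone; camera adjusted p = 0.301), with Csf1r, the receptor for macrophage colony-stimulating factor, falling from 63.3 ± 7.96 to 41.9 ± 1.33 CPM. Of 22 antigen presentation genes 2 rose and 3 fell (4 and 4 adjusted over the list alone; camera adjusted p = 0.918), with H2-DMa, a peptide loading chaperone, falling from 389.6 ± 25.7 to 191.9 ± 30.5 CPM. Of 30 Toll-like and inflammasome sensors 0 rose and 3 fell (0 and 4 adjusted over the list alone; camera adjusted p = 0.653), with the protease gene Casp1 falling from 52.3 ± 1.86 to 31.5 ± 3.46 CPM. Of 20 genes of alternative activation 3 rose and 1 fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.946), with the transglutaminase gene Tgm2 rising from 78.0 ± 18.7 to 232.2 ± 17.8 CPM. For GM-CSF, TGF-beta and transcription factor genes, 3 of 24 rose and 1 fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.524), and for NF-kappaB feedback genes 0 of 18 rose and 1, Nfkb1, fell (0 and 0 adjusted over the list alone; camera adjusted p = 0.344). Nfkb1 lost its call without each of the 6 libraries in turn (edgeR adjusted p = 0.105, 0.0775 and 0.0946 for control replicates 1, 2 and 3 and 0.121, 0.0755 and 0.0689 for knockout replicates 1, 2 and 3). For glycolysis and hypoxia 4 of 27 rose and 0 fell (7 and 1 adjusted over the list alone; camera adjusted p = 0.0681), with the hexokinase gene Hk1 rising from 4.31 ± 0.684 to 10.7 ± 1.27 CPM. For NRF2 targets 5 of 26 rose and 1 fell (5 and 1 adjusted over the list alone; camera adjusted p = 0.0563), for lysosomal genes 5 of 39 rose and 3 fell (7 and 5; camera adjusted p = 0.629), and for autophagy 1 of 31 rose and 2 fell (1 and 2; camera adjusted p = 0.629). For the unfolded protein response 1 of 23 rose and 3 fell (1 and 5 adjusted over the list alone; camera adjusted p = 0.14), and the 1 that rose was Xbp1, its transcription factor, from 511.5 ± 39.0 to 1217 ± 115.1 CPM. For immediate early genes 2 of 19 rose and 3 fell (7 and 3 adjusted over the list alone; camera adjusted p = 0.204), for partners of protein kinase C and RACK1 signalling the camera adjusted p over 23 genes was 0.799, and for nuclear retained long RNAs 1 of 8, Malat1, rose and 0 fell (1 and 0 adjusted over the list alone; camera adjusted p = 0.311). Malat1 lost its call without control replicates 2 or 3 or knockout replicates 1 or 2 (edgeR adjusted p = 0.116, 0.083, 0.0834 and 0.0684).

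Of 41 lists fixed before the data were examined, 40 had at least 5 tested genes and 8 were called by camera with the preset correlation, 0 with an estimated correlation and 8 by fry, with integrated stress response, immediate early and lipid efflux genes in place of proliferation, oxidative phosphorylation and airway epithelium. The fry method tests whether a list's genes move one way without comparing them with other genes. The median, the mean and the direction of the test did not all have 1 sign in the lists of alveolar macrophage identity, translation factors, ribosome quality control, antigen presentation, fatty acid oxidation, phospholipid catabolism, phagocytosis receptors and dendritic cell markers, none of them called.

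Markers of other cells were read as a check of what else the libraries held. Airway epithelial genes were lower as a list by camera with the preset correlation, but not by fry (adjusted p = 0.25) or by camera with an estimated correlation (adjusted p = 0.75), with 0 of 8 higher and 2 lower, also adjusted over the list alone. Bpifa1, a secreted airway protein gene, fell from 103.1 ± 11.5 to 32.2 ± 16.3 CPM (SD, n = 3 per group). The median was -0.97 (camera, preset correlation, Benjamini-Hochberg adjusted p = 0.0454). The call was lost without control replicate 1, control replicate 3, knockout replicate 2 or knockout replicate 3 (camera adjusted p = 0.0819, 0.19, 0.056 and 0.0933), with median-of-ratios scaling (0.05) and with a GC and length correction (0.0522), and the median was -0.59 without knockout replicate 3. Alveolar type 2 cell genes went both ways, with 2 of 13 higher and 3 lower (2 and 4 adjusted over the list alone; camera adjusted p = 0.301). Sftpc, a surfactant protein gene with a log2 fold change of 1.62 and of 1.02 without knockout replicate 3, stood at 2.16 to 6.03 CPM in control and 6.75 to 18.5 CPM in knockout, and lost its call without control replicates 1 or 3 or knockout replicates 2 or 3 (edgeR adjusted p = 0.144, 0.131, 0.0631 and 0.165). Of 14 neutrophil markers 2 rose and 3 fell (4 and 3 adjusted over the list alone; camera adjusted p = 0.344), with Csf3r, the granulocyte growth factor receptor, falling from 9.20 ± 1.35 to 3.12 ± 1.44 CPM. For T and NK cells 1 of 17 rose, for B and plasma cells 0 of 8, for dendritic cells 0 of 15, for endothelium and mesenchyme 1 of 17 and for erythroid cells and platelets 0 of 8, and 0, 0, 1, 2 and 0 fell (edgeR; camera adjusted p = 0.301, 0.404, 0.799, 0.172 and 0.21). Adjusted over the list alone, 0, 0, 0, 1 and 0 were higher and 0, 0, 1, 3 and 0 lower. With scaling to library totals the erythroid and platelet list was called higher (median 0.54, camera adjusted p = 0.032). The marker of T and NK cells that rose was Ccl5, and its call was lost without any control library or knockout replicates 2 or 3 (edgeR adjusted p = 0.142, 0.0913, 0.071, 0.138 and 0.13). The dendritic cell marker that fell was Batf3. Of 4 tested markers of eosinophils, basophils and mast cells 1 was higher and 1 lower, too few for a list test. The beta-globin gene Hbb-bs stood at 19.1, 142 and 21.4 CPM in control replicates 1, 2 and 3 and at 201, 109 and 124 CPM in knockout replicates 1, 2 and 3.

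Transcripts of intestinal epithelium were present in all 3 control libraries and lower in knockout, a pattern found after the values were seen. Of 44 colon epithelium genes listed then, 41 were in the table and 31 tested, and 18 of these were lower in knockout and 0 higher. Counts in all 3 control libraries were found for 33 of the 41 and counts in all 3 knockout libraries for 6, and 18 had no count in knockout. Their sums were 45.4, 43.1 and 47.3 CPM in control replicates 1, 2 and 3 and 10.9, 13.1 and 15.6 CPM in knockout replicates 1, 2 and 3. Most of the knockout sums came from Slc26a2, Prdm16 and Cldn7, which were not called. Their means were 4.46, 3.26 and 2.33 CPM in knockout and 5.39, 1.64 and 1.70 CPM in control. Muc2, the main intestinal mucin gene, stood at 3.59 ± 2.75 CPM in control and 0.0145 ± 0.0252 CPM in knockout (SD, n = 3 per group). Cdh17, an intestinal cadherin gene, was at 1.19 ± 0.0666 CPM in control and had no count in knockout, so that it was at least 4.77-fold lower against a floor of 3 read pairs per library. The smooth muscle gene Myh11 was at least 5.02-fold lower on the same footing. Of the 889 genes lower in knockout, 82 had no count in any knockout library, with control means of 0.174 to 4.31 CPM, and 10 of the 878 higher genes had none in any control library. Without them 807 genes were lower and 868 higher. Floors cover counting error only.

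**Figure D3:**
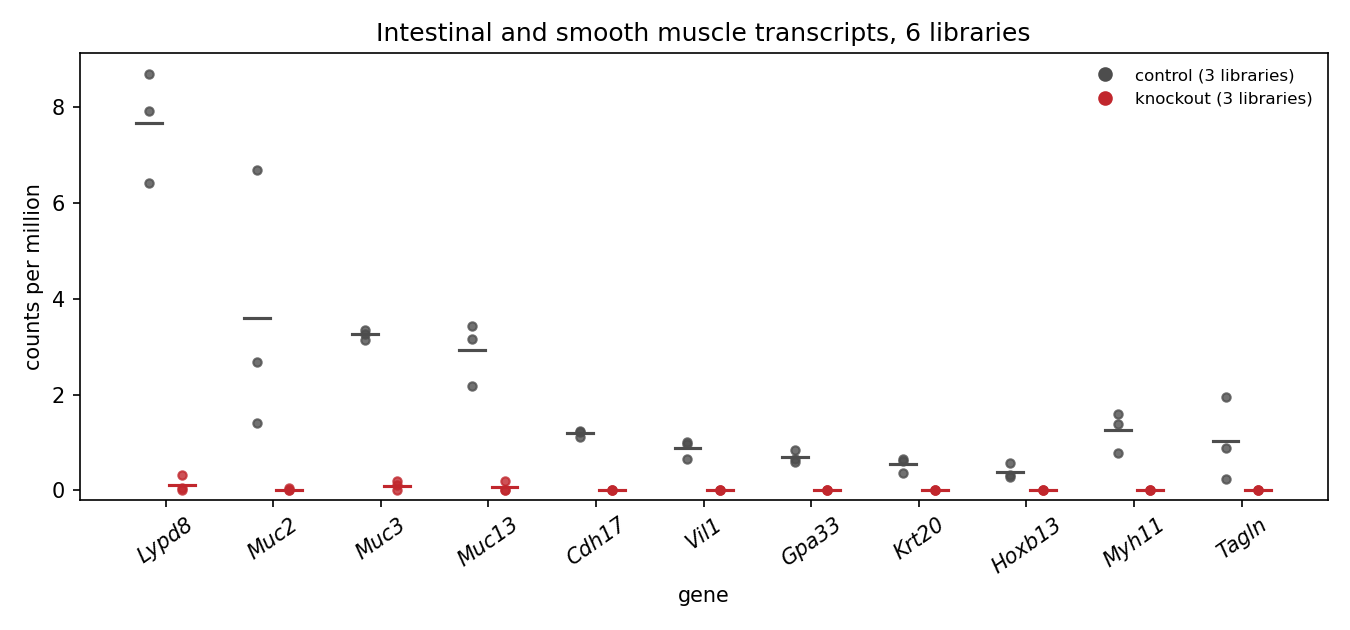
Counts-per-million values of 9 intestinal epithelial and 2 smooth muscle transcripts (Myh11 and Tagln) in each of the 6 libraries, with control in grey, knockout in red and group means as horizontal bars. Lypd8 had a mean of 7.67 CPM in control and 0.121 CPM in knockout.

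Tests of the annotation carried by the deposited table gave 53 terms enriched among higher genes and 9 among lower genes (one-sided Fisher's exact test, Benjamini-Hochberg adjusted within source and direction). Among higher genes, the cellular response to interferon-beta had 12 of 33 tested genes called against 2.0 by chance (adjusted p = 0.000187, Fisher's exact test), with Irgm1, an interferon-inducible GTPase gene, rising from 8.50 ± 0.379 to 17.7 ± 3.28 CPM. Neutrophil degranulation, a broad set of granule and membrane proteins that macrophages also express, had 60 of 437 against 29.8 (adjusted p = 6.9e-05, Fisher's exact test). It also had 52 of 437 among lower genes against 33.4 (adjusted p = 0.117, Fisher's exact test), and its call was lost among genes higher by at least 2-fold (29 of 437, adjusted p = 0.0575). PPAR signaling had 15 of 58 against 4.5 (adjusted p = 0.00608, Fisher's exact test). Among lower genes, fatty acid beta-oxidation had 10 of 36 against 2.3 and NAD binding 10 of 37 against 2.4 (adjusted p = 0.0318 for both, Fisher's exact test), with Idh1, a cytosolic isocitrate dehydrogenase gene, falling from 128.9 ± 6.50 to 82.6 ± 6.77 CPM. Positive regulation of phagocytosis had 7 of 15 against 1.0 (adjusted p = 0.012, Fisher's exact test), among them Sirpb1a, Sirpb1b and Sirpb1c, near-identical receptor genes whose reads cannot be fully parted. Sirpb1a lost its call without control replicates 1 or 2 or knockout replicate 3 (edgeR adjusted p = 0.0662, 0.0717 and 0.0601). The KEGG cell cycle had 22 of 119 against 9.2 (adjusted p = 0.0253, Fisher's exact test). Among genes lower by at least 2-fold these calls were lost, with 0 of 36, 2 of 37, 1 of 15 and 5 of 119 genes (adjusted p = 1, 1, 1 and 0.958, Fisher's exact test). Keratinocyte differentiation had 9 of 17 against 1.1 (adjusted p = 0.000556, Fisher's exact test), intermediate filament 9 of 25 against 1.6 (adjusted p = 0.012), and keratinization and the cornified envelope, with the same genes, 9 of 21 against 1.6 (adjusted p = 0.00513). Of the 9 genes of each, 4 had a knockout mean under 0.1 CPM. Apical plasma membrane had 21 of 131 against 8.5 (adjusted p = 0.0318, Fisher's exact test), but 15 of the 21 had a knockout mean under 0.1 CPM, and without such genes 6 of 113 were called against 6.5. Irgm1, Idh1 and the Sirpb1 genes were chosen after their values were seen.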

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

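The alternatives of scaling to library totals, counts divided by 4, a GC and length correction, a minimum of 10 CPM and leaving out genes at 0 in 1 whole group were chosen only after the results were seen. Rack1 was called lower under each of the 24 alternatives, with log2 fold changes from -1.46 to -1.0, and -1.16 to -1.07 with each library left out. Against 878 genes higher, limma, which tested 7882 genes, called 239, 230 and 236 in all on log2(FPKM + 1), + 0.1 and + 0.5, 256 on FPKM rescaled to 1 sum, 252 with robust fitting and, on 26428 genes, 41 without a filter. Library totals gave 290 higher, a mean FPKM of at least 5 gave 513, with fewer genes tested, and a change of at least 2-fold 456. Against 889 genes lower, robust fitting gave 1398, library weights 4972, no filter 131, the mean FPKM of at least 5 gave 466 and a change of at least 2-fold 304. The library weights stopped before convergence. They gave control replicate 2 a weight of 15.2, against 0.208 to 2.97 for the other libraries. Limma shared 861 of the 1346 main calls it tested, and 1249 on FPKM divided by size factors. There it called 727 higher and 674 lower, and 705 and 858 after quantile normalization, so the excess of lower calls on FPKM as deposited came with its scaling (shift of all genes -0.29, against 0.03 and 0.01). Leaving out each library gave 455 to 691 higher and 372 to 565 lower, with fewer samples. DESeq2 called 1133 and 1187, with 1761 of the 1767 main calls among them. With an estimated correlation 0 gene lists were called by camera, and fry called 8. Camera adjusted p was then 0.52 for inflammatory genes (median 0.76), pro-fibrotic genes (0.61) and apoptosis and p53 (0.41), 0.62 for interferon-stimulated genes (1.17) and heat shock (0.54), 0.64 for proliferation (-0.55) and oxidative phosphorylation (-0.25) and 0.75 for airway epithelium (-0.97). By fry the adjusted p was 0.1 for proliferation, 0.13 for oxidative phosphorylation and 0.25 for airway epithelium. Apoptosis and p53 had a median of 0.05 (camera adjusted p = 0.0723) with limma without a filter, 0.37 (0.115) at a mean FPKM of at least 5, and 0.26 to 0.47 with each library left out. Airway epithelium had -0.98 (camera adjusted p = 0.05) with median-of-ratios size factors, -0.99 (0.0522) with the GC and length correction and -1.24 to -0.59 with each library left out; at a mean FPKM of at least 5 or 10 CPM it had too few genes for a value. Over all alternatives medians ran from 0.07 to 1.25 for inflammatory genes, 0.20 to 1.34 for interferon-stimulated genes, 0.10 to 1.04 for pro-fibrotic genes, 0.13 to 0.63 for heat shock, -0.92 to -0.38 for proliferation and -0.71 to -0.20 for oxidative phosphorylation. Lower annotation terms numbered 28 at a change of at least 2-fold against 9, without fatty acid beta-oxidation, NAD binding, positive regulation of phagocytosis and the KEGG cell cycle. With library weights, log2 fold changes changed sign for Sftpc (-0.08) and S100a8 (-0.59). Except for scaling and where the number of genes or samples tested fell, the cause was not tested. With the replicate number as a block, 770 genes were higher and 699 lower; samples with the same number shared no deviation (r 0.03, -0.04 and 0.00 across genes), and not every library correlated best with its own number, so the numbers do not pair the samples. Depth limits genes near the floors of 0.14 to 0.29 CPM.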

Other observations

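The tests of intestinal transcripts, Cxcr1 and Cxcr2, and interferon-stimulated genes were chosen only after the result was seen, and the splits of the libraries were planned. Class I histocompatibility genes were among those higher in knockout. H2-Q7 and H2-Q6, which encode class Ib proteins, had log2 fold changes of 2.20 and 1.56 (edgeR adjusted p = 0.000654 and 0.00279), and their reads cannot be fully parted from those of near-identical copies. The KEGG term antigen processing and presentation had 13 of 59 tested genes called higher against 4.5 by chance (adjusted p = 0.0177, Fisher's exact test), a call lost among genes higher by at least 2-fold (8 of 59, adjusted p = 0.0661). Not all of the 13 are class I genes, as Hsp90ab1, Hspa1a, Hspa1b, Hsp90aa1 and Lgmn are among them. The antigen presentation list fixed beforehand had 2 of 22 genes higher and 3 lower (camera adjusted p = 0.918).

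Terms with carbonic anhydrase and arachidonic acid genes were enriched among higher genes. Nitrogen metabolism had 5 of 11 tested genes called against 0.8 by chance (adjusted p = 0.0188, Fisher's exact test). Of these Car13 and Car5b, a cytosolic and a mitochondrial carbonic anhydrase gene, had log2 fold changes of 1.90 and 1.17, and Glul, the glutamine synthetase gene, 1.40 (edgeR adjusted p = 0.00203, 0.0062 and 0.000731). Arachidonic acid metabolism had 10 of 37 called higher against 2.8, and 2 lower (adjusted p = 0.0177, Fisher's exact test), with the cyclooxygenase gene Ptgs1 at 1.54 and the epoxide hydrolase gene Ephx2 at 3.33 (edgeR adjusted p = 0.00013 and 0.000131). These genes were chosen after their values were seen.

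Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many higher genes as the real split (878, highest other 0), 1 as many lower genes (889, highest other 0) and 4 as many called lists (8, highest other 11). With 0 genes by edgeR, the other splits had 231 to 468 genes at an unadjusted p under 0.05, against 3755. With 10 splits a share under 0.05 is impossible. The other splits still gave 2 to 11 lists called by camera with the preset correlation. The number of called lists therefore did not set the real split apart. A small camera p-value at that correlation is not by itself evidence of a difference between the groups.

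Intestinal transcripts stood in all 3 control libraries and lower in knockout. Some values go against colon RNA as the source of all lower calls, but its test could not decide. In all, 49 lower genes, 11 of them lower by at least 2-fold, lost more than 10 times 7.67 CPM, the highest control level of a colon marker (Lypd8). This limit by construction also lies above the 43.1 to 47.3 CPM that the whole colon list summed to in control. Rack1, the targeted gene, and Siglecf, used to identify these cells, also fell. The count of 49 did not reach the bound of its test, and no colon profile was measured. The share of lower calls that colon RNA accounts for therefore stays open. Alveolar type 2 cells carried over into the control libraries stay open, and so does airway epithelium. Sftpc went the other way (log2 fold change 1.62, SE 0.44, and 1.02 without knockout replicate 3). Its call ended without control replicates 1 or 3 or knockout replicates 2 or 3 (edgeR adjusted p = 0.144, 0.131, 0.0631 and 0.165). Sftpa1, a second surfactant protein gene, also stood higher in knockout, at 1.18 to 5.08 CPM against 0.257 to 0.746 CPM in control. But 3 of the 13 tested type 2 markers fell, Epcam among them. The mean of that list was -0.84 to -0.26 in knockout and -0.16 to 0.29 in control. Colon tissue RNA may be present, with smooth muscle markers at a median of -1.03 (spread 0.50, from the median absolute deviation over the square root of n = 9), and so may reads leaked from 1 colon library, with a chi-square of 4.0 per degree of freedom over 27 colon markers (2.8 without Muc2), reached by 6.5% of 1000 random sets of genes with as many read pairs. The bounds of the leak, Sftpc and colon tests were changed after the values were seen, each toward leaving the explanation open, and the knockout genotype was not tested.

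Cxcr1 and Cxcr2 are also neutrophil genes. Neutrophils in the knockout libraries would bring S100a8 and S100a9, abundant transcripts of those cells, which together were 7.40 CPM higher (SE 4.51) against rises of 57.8 CPM (SE 8.73) for Cxcr1 and 18.0 CPM (SE 3.57) for Cxcr2. By these 2 transcripts alone, the values argue against neutrophils as the source of Cxcr1. Cxcr2 exceeded S100a8 and S100a9 by less than 2 standard errors and stays open. Other neutrophil genes went both ways. Csf3r fell (log2 fold change -1.55) and Ly6g had no count in knockout and 0.218 CPM in control, near the floor. Retnlg, a neutrophil gene, stood at 44.1 to 63.2 CPM in knockout and at 0 to 11.9 CPM in control. Its knockout level was near that of Cxcr1, which had means of 61.1 CPM in knockout and 3.28 CPM in control. Neutrophils as a source of Cxcr1 are therefore not excluded. The lowest knockout library had 12.8 times the Cxcr1 level of the highest control library, and knockout genotype stays open.

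Interferon-stimulated genes were highest in knockout replicate 2. Without that library the list median was 0.71, and with a GC and length correction it was 1.18, against 1.17 in the main fit. The mean log2 value of the list was 0.72 and 0.96 in knockout replicates 1 and 3, against -0.06 to 0.04 in control. These sizes argue against that library alone and against GC content and length as the whole cause. The camera adjusted p-values at the preset correlation (2.91e-10 and 2.96e-11) carry no weight here, since other splits of the libraries also gave called lists. With an estimated correlation the camera adjusted p of the uncorrected list was 0.62. The lowest knockout library lay 0.68 above the highest control library in the mean log2 value of the list. The knockout genotype may account for this, and so may handling or a batch that the labels do not give.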
